A study of Mus musculus with 4 samples.

How the data were processed

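Each of the 4 groups (WT vehicle, TCKO vehicle, WT vaccine, TCKO vaccine) was a 5' single-cell gene expression library of marrow cells, with 1 library per group. The deposited files hold UMI counts per gene and barcode, made by the authors with Cell Ranger 7.0.1 on mm10 per the submitters' processing notes, for barcodes already called as cells. They list 32285 genes, of which 32235 were found by identifier in GENCODE release M21 (GRCm38), which gave positions and gene types. Whether different lanes or days were used, and the number of mice per library, was not given in the sources used here.

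Barcodes with at least 300 genes and at most 10% mitochondrial UMIs were kept. In the order of the groups above, 10, 11, 1 and 11 barcodes had too few genes and 50, 28, 2 and 40 too many mitochondrial UMIs. Scrublet, as built into scanpy, scored doublets, and per library the highest scores were removed at 0.8% per 1000 barcodes, which took 414, 466, 512 and 611 and left 6725, 7124, 7485 and 8078 cells. Median UMIs per barcode were 5721, 7326, 5818 and 6638, median genes 2268, 2639, 2282 and 2457 and the median mitochondrial share 1.67, 1.47, 1.46 and 1.57%. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes were chosen without receptor V, D and J, immunoglobulin, ribosomal, mitochondrial, Xist, Tsix and Y-linked genes. Clusters came from 30 principal components, 15 neighbours and Leiden resolution 1, without integration across libraries, and T-like cells were clustered again in the same way. Versions were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.

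The 22 marker lists were written before the data were examined, as were the 20 gene lists, the comparisons, the rule for named genes, the filters and the 40 alternatives tried. The shares of cells at which a marker names a cluster were set after seeing the data: a cluster was T-like with at least 3 of 7 T cell markers each in at least 70% of its cells, and T-like clusters were named by Foxp3 in at least 40%, Cd4 in 50%, Trdc in 50% or Cd8b1 in 60% with Cd4 in at most 15% of cells. Clusters with Mki67 in at least 50% of cells, clusters led by rRNA-like models, and clusters whose 10 leading genes held more markers of another class kept no name. Unnamed cells were 7.91, 6.25, 3.42 and 6.51% of kept cells outside and 28.5, 31.4, 26.8 and 30.4% of T-like cells within the T-like group. Neutrophil-like cells were 2.26, 1.74, 2.26 and 1.40% and neutrophil precursor-like cells 0.595, 0.421, 1.47 and 0.582% of kept cells. The planned background of B-like cells could not be used, as no B-like cluster was found, and neutrophil-like cells took its place. A T cluster led by Isg15 and Ifit3 (T cluster 3) was among those left unnamed, so interferon-rich cells of CD8 and CD4 type lie partly outside the named classes. It held 3.02, 7.20, 2.16 and 5.29% of T-like cells. The genotype comparisons of the named classes therefore leave out more of these cells in TCKO than in WT.

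UMIs were summed over the cells of a class and library and divided by all gene UMIs of that class and library and scaled to CPM, with exact 95% Poisson intervals. Shares have exact (Clopper-Pearson) 95% binomial intervals, and a count of 0 allows up to 3 counts. Genes with at least 100 UMIs over the 2 libraries compared were used (50 in the splits by sex or cluster), and sizes of 1.5-fold and 2-fold describe ratios without a test, as a group of 1 library has no spread. The 4 comparisons were vaccine against vehicle in WT and in TCKO, and TCKO against WT with vehicle and with vaccine, in CD8 T-like and CD4 T-like cells. For the vaccine contrast in TCKO minus WT a list's value is the median of its members' differences, which need not equal the difference of the medians. A list's median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of mean CPM, which describes these libraries and is no test. Lists with fewer than 5 members above the minimum got member values only. The lists were cytotoxic effector, naive and central memory, exhaustion and inhibitory receptors, activation after antigen receptor signalling, type I and type II interferon response, MHC class I, MHC class II, cell cycle, reported miR-155 targets, glycolysis, oxidative phosphorylation, homing and chemokine receptors, helper and regulatory T programs, ribosomal proteins, mitochondrial transcripts, dissociation and heat shock stress, and free RNA from red cells, from neutrophils and from B and plasma cells. Socs1 and Maf also sit on the miR-155 target list, and Ciita, Tbx21, Ifng, Il10 and Egr1 are further members that lists share.

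Genes were named by a fixed rule: Mir155hg, then up to 4 members of each list whose median lay under percentile 5 or over percentile 95 or in which at least 25% of members differed by 1.5-fold, then the 6 highest and 6 lowest ratios per comparison and class, leaving out receptor V, D and J, immunoglobulin, Gm and Rik, mitochondrial, Xist, Tsix and Y-linked genes. The 5 highest and 5 lowest differences between the genotypes' vaccine contrasts and 3 Trbv genes per genotype and class were named in the same way. The report gives a part of these genes. Ighm and Cd79b, S100a8, S100a9 and Igkc in CD4 T-like cells, the statements on UMIs within a few cells, and leading genes of clusters were added after their values were seen. For 14 genes the share of CD8 T-like cells with a UMI was taken after thinning each cell to 1500 UMIs.

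The steps were tested on simulated data with known changes, drawn at the depth of each comparison and class. Of unchanged genes 0 to 1 reached 2-fold, 93.9 to 100% of genes changed 2-fold were found at 1.5-fold or more with the right sign but 40.3 to 68.7% at 2-fold, and 33.3 to 56.1% of genes changed 1.5-fold at 1.5-fold, which 12 to 66 unchanged genes also reached. By construction, intervals covered 95.1 to 95.8% of true values. An unchanged list fell at percentile 24.6 to 85.8. A list with 0.3 added to its log2 ratios fell at percentile 100, all but certain at an SD of 0.12 to 0.19.

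Alternatives were a mitochondrial limit of 5%, no doublets removed, Leiden resolutions 0.5 and 2.0, a minimum of 500 genes, cells gated by their own Cd8a, Cd8b1 and Cd4 UMIs, edgeR's TMM factors, DESeq2's size factors, minimums of 20 and 300 UMIs, the mean over cells, other thinning, and leading Trbv genes per cell. After seeing the data, 5 were added: clusters without the interferon genes for shares and for list medians, cells split by Xist and 4 Y-linked genes for shares and for list medians, and each cluster of a class alone. Classes with at least 100 cells in every library other than CD8 and CD4 T-like cells were computed in the same way, and their gene lists enter only the closing section, and mature microRNA, receptor clonotypes and surface proteins were not analysed here.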

Results

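Single-cell RNA of bone marrow T cells was counted in 4 libraries from mice that carried C1498-OVA, an acute myeloid leukaemia line engineered to express ovalbumin (OVA) as a model tumour antigen. The groups crossed genotype with treatment and held 1 library each: WT vehicle, TCKO vehicle, WT vaccine and TCKO vaccine. TCKO mice carried floxed Mir155 alleles and a CD4-Cre driver, which deletes the gene in T cells, and WT mice were floxed littermates without Cre. The vaccine was OVA mRNA in a transfection lipid at 2.5 µg per dose, and the vehicle was the same mixture without RNA. Per the labels, doses were given on days 1 and 7 and leukaemia cells on day 21, while other label text puts treatment after challenge, so the order remained unsettled here. The labels describe the sorted cells both as CD45+ and as CD45+ CD3+ cells, and 89.2, 91.6, 92.9 and 91.5% of the kept cells were T-like (order of libraries as above, here and in later lists of 4 values). The libraries held 7199, 7629, 8000 and 8740 barcodes with 46355335, 62655011, 52240850 and 64226229 unique molecular identifiers (UMIs). The lowest UMI count of a barcode was 1757 in the WT vaccine library against 500 or 501 in the others. Every library held cells of both sexes: 25.3, 32.6, 11.5 and 13.2% of T-like cells had a UMI of a Y-linked gene and none of Xist, and 39.0, 36.8, 49.4 and 39.5% had a UMI of Xist and none of a Y-linked gene. Without replicate libraries no difference between groups was tested. Values in square brackets are 95% intervals for counting error only, not UMIs clumped in few cells or variation between mice.

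Mir155hg (ENSMUSG00000097418), the host transcript from which miR-155 is processed, lies on chromosome 16 at 84703167 to 84715245 of mm10 on the plus strand and was counted to ask whether the genotype labels showed in the RNA. In all T-like cells it stood at 6.08 [5.33 to 6.91] CPM (UMIs scaled to one total per class and library, as are all later gene levels) in the WT vehicle library and 6.28 [5.57 to 7.06] in the WT vaccine library. It was lower in both TCKO libraries, at 2.30 [1.91 to 2.74] with vehicle and 2.50 [2.09 to 2.96] with vaccine. CD8 T-like cells gave 3.61 [2.71 to 4.70] (WT vehicle), 1.58 [1.13 to 2.17] (TCKO vehicle), 4.56 [3.71 to 5.55] (WT vaccine) and 1.80 [1.32 to 2.40] (TCKO vaccine). Regulatory T-like cells had the highest level, 20.2, 5.95, 20.8 and 6.36, and CD4 T-like cells had 8.99, 0.959, 9.62 and 4.8, where the TCKO vehicle value rested on 3 UMIs and reached up to 2.80. Counts from 5' ends need not cover the floxed part of the gene, so the remaining TCKO counts do not measure undeleted alleles.

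**Figure D1:**
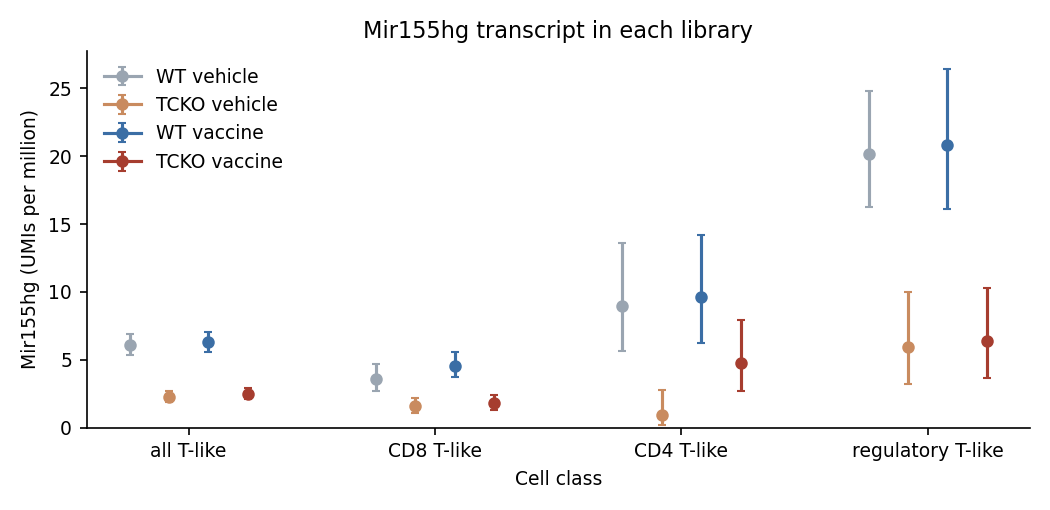
Mir155hg in CPM (vertical axis) for 4 cell classes (horizontal axis), with a point per library and bars for the exact 95% Poisson interval. In all T-like cells the WT libraries lie at 6.08 and 6.28 and the TCKO libraries at 2.30 and 2.50.

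Class shares asked how the make-up of the marrow T cells differed with vaccine and with miR-155 loss. The CD8 T-like share of T-like cells was lowest in the WT vehicle library, at 37.1% [35.9 to 38.4], against 50.3% [49.1 to 51.5] with vaccine in WT, 47.4% [46.2 to 48.6] in TCKO with vehicle and 48.3% [47.2 to 49.4] in TCKO with vaccine. Within TCKO the vaccine and vehicle intervals overlapped, and with vaccine the TCKO and WT intervals also overlapped. Regulatory T-like cells, which carry Foxp3, the gene that directs the regulatory program, were most frequent in the WT vehicle library. They made up 19.9% [18.9 to 20.9] of T-like cells there, 10% [9.30 to 10.7] in WT with vaccine, 7.00% [6.40 to 7.65] in TCKO with vehicle and 7.49% [6.90 to 8.12] in TCKO with vaccine. Among CD4 and regulatory T-like cells together the regulatory share was 66.9, 42.9, 56.4 and 46.8%. Cells with a Foxp3 UMI, counted without clusters, were 15.6, 6.22, 9.41 and 5.87% of T-like cells. In neutrophil-like cells, taken as a background for free RNA, the share was 0.658% in the WT vehicle and 5.92% in the WT vaccine library, and no cell of 124 or 113 had a Foxp3 UMI in the TCKO libraries, which allows up to 2.93% and 3.21%. Median UMIs were 3383, 4581, 3870 and 4124 in regulatory T-like cells and 6376, 7323, 5974 and 6649 in CD8 T-like cells. CD4 T-like cells other than regulatory cells were 9.83, 9.33, 7.74 and 8.54% and gamma delta T-like cells 4.62, 4.86, 5.12 and 5.30%. In the split by sex-linked UMIs, regulatory T-like cells were 19.3, 5.99, 9.38 and 6.51% of cells with Xist UMIs only and 16.8, 7.05, 11.0 and 8.30% of cells with Y-linked UMIs only. The CD8 T-like shares in the same split were 32.1, 45.6, 46.1 and 44.3% and 39.8, 46.3, 47.1 and 52.7%. CD4 T-like shares moved with clustering and gating, as given in the closing section. All these shares describe the cells recovered after sorting rather than numbers in the marrow.

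**Figure D2:**
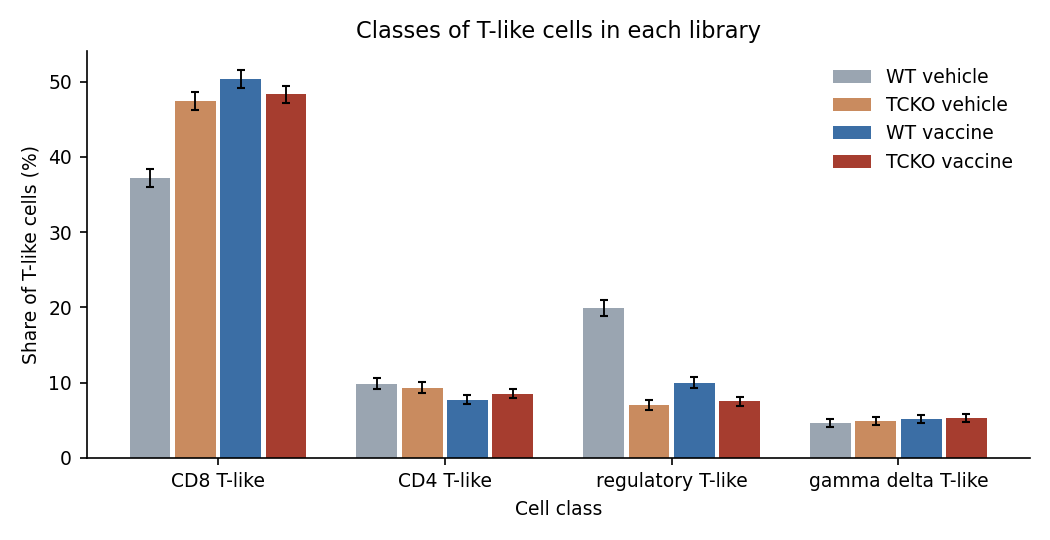
Share of T-like cells in percent (vertical axis) for 4 classes (horizontal axis), with a bar per library and error bars for the exact 95% binomial interval. The WT vehicle library has the lowest CD8 T-like bar, 37.1%, and the highest regulatory T-like bar, 19.9%.

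**Figure D3:**
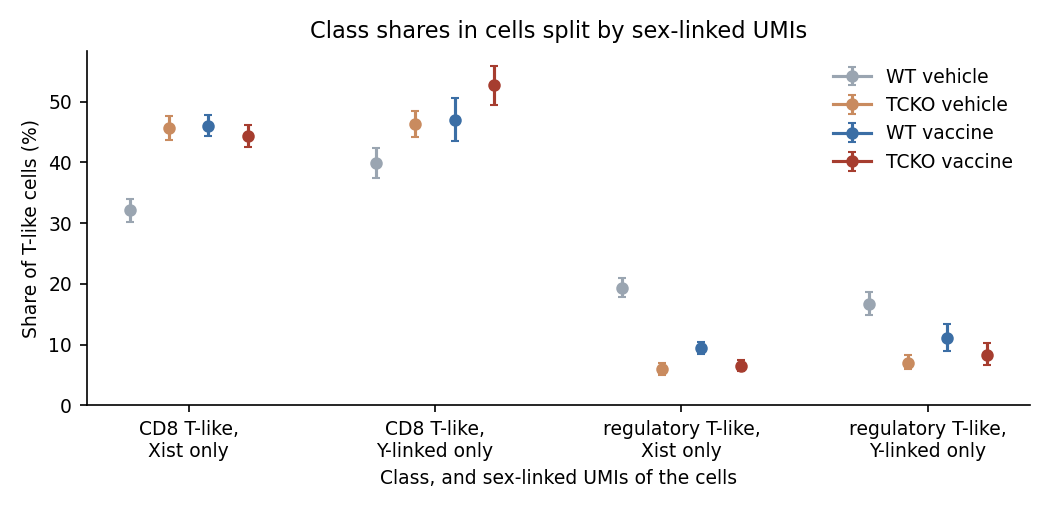
Share of CD8 T-like and regulatory T-like cells in percent (vertical axis) among T-like cells with Xist UMIs only or Y-linked UMIs only (horizontal axis), with a point per library and exact 95% binomial intervals. Regulatory T-like cells of the WT vehicle library lie at 19.3% and 16.8%, the highest point of each split.

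Different clusters held most of a class in some libraries. Of CD8 T-like cells, T cluster 1 (led by Ccr7, Lef1, Dapl1 and Klf2) held 23.8, 41.1, 40.8 and 37.6%. T cluster 13 (Lef1, Ccr7, Themis and Bach2) held 37.9, 30.7, 29.0 and 34.9%. T cluster 9 (Ccl5, Nkg7 and Gzmk) held 16.8, 5.88, 15.9 and 9.41%. T cluster 2 (Ly6c2, Nkg7 and Ccl5) held 16.9, 15.8, 8.81 and 11.6%. Of CD4 T-like cells, T cluster 7, led by Lef1, Ccr7, Bach2 and Satb1, held 36.8, 72.4, 57.8 and 59.9%, and T cluster 8, led by Ly6a, Itgb1 and S100a6, held 63.2, 27.6, 42.2 and 40.1%. In the WT vehicle library the CD4 class was therefore mostly cluster 8, and in the other libraries it was mostly cluster 7. Values within these clusters stand beside the class values where the direction or size differed.

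The first comparison asked which genes distinguished T cells after OVA mRNA vaccination from T cells after vehicle in mice with intact miR-155. CD8 T-like cells of the vaccine library had higher levels of genes of resting, recirculating T cells. The chemokine genes Ccl3 and Xcl1, the granule protease gene Gzmm and the killer-cell receptor genes Klrc2 and Klra9 were lower with vaccine. The gut-homing receptor gene Ccr9, the egress receptor gene S1pr1, the interleukin-7 receptor gene Il7r and Dapl1 were higher. In CPM, vaccine against vehicle, Ccl3 stood at 8.07 [6.93 to 9.35] against 17.2 [15.2 to 19.5], Gzmm at 30.1 against 49.7, Klrc2 at 3.06 against 5.74 and Klra9 at 2.19 against 6.88. Xcl1 stood at 32.6 against 98.6, but 772 of its 1476 UMIs in the vehicle library lay in 1 cell. Prdm1, which encodes the effector regulator Blimp-1, went the other way, at 5.98 against 3.54. The cytotoxic effector list had a median log2 ratio of -0.15 over 29 members, at percentile 0 of random lists, with 1 member at least 1.5-fold higher and 5 lower. Its direction depended on the cells taken: 0.14 and -0.16 in cells with Xist or Y-linked UMIs only. The median was 0.048 and 0.074 within T clusters 13 and 9, and -0.86 over 18 members without T cluster 9. The naive and central memory list had a median of 0.15 over 19 members at percentile 99.99, with Ccr9 at 73.6 [70.0 to 77.3] against 39.0 [35.9 to 42.3], S1pr1 at 254 against 197, Il7r at 745 against 629 and Dapl1 at 319 against 267. It was 0.063 in cells with Xist UMIs only, 0.082 within T cluster 1, 0.053 within T cluster 13 and 0.29 in cells gated by their own Cd8a, Cd8b1 and Cd4 UMIs. The homing list had a median of -0.065 over 16 members at percentile 1.72, with 2 at least 1.5-fold lower. In it the collagen-binding integrin gene Itga1 stood at 2.87 against 5.94 and the inflammatory chemokine receptor gene Ccr2 at 24.6 against 36.3. Among the highest ratios were the kinase gene Camk2b at 20.1 [18.3 to 22.1] against 4.07 [3.12 to 5.23], Greb1l at 3.695 against 1.34, Cul7 at 3.6 against 1.67 and Cdk5rap1 at 50.4 against 23.4.

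The other lists were read in the same comparison of CD8 T-like cells, vaccine against vehicle in WT. The type I interferon response list had a median of -0.013 over 40 members at percentile 12.3 (-0.15 at percentile 0 in cells with Xist UMIs only, 0.049 in cells with Y-linked UMIs only), the type II list 0.025 at percentile 49.995, and activation after antigen receptor signalling 0.0016 at percentile 37.9. Exhaustion and inhibitory receptor genes had a median of -0.10 at percentile 8.38 (0.16 at percentile 95.6 in cells with Xist UMIs only), cell cycle genes 0.047 at percentile 77.1 and reported miR-155 targets 0.0075 at percentile 38.5. Medians were 0.011 for glycolysis, 0.030 for oxidative phosphorylation, -0.0095 for MHC class I, -0.038 for helper and regulatory programs and -0.018 for ribosomal proteins. Stress genes had a median of 0.098 at percentile 97.8 with members on both sides, as the immediate early gene Fos stood at 2.55 against 6.81 and the chaperone gene Dnaja1 at 425 against 292. Mitochondrial transcripts, read as a measure of RNA quality, had a median of -0.16 at percentile 0. Neutrophil RNA was lower with vaccine, with S100a8 at 7.48 against 12.9 and Camp at 3.10 against 6.34. Haemoglobin RNA was lower as well, with Hba-a1 at 2.01 against 26.4 and Hbb-bs at 4.06 against 49.9, but 96.4% of the 779 Hbb-bs UMIs of T-like cells in the vehicle library lay in 10 cells. Of B and plasma cell genes only Ighm, at 212 against 197, and Cd79b, at 19.5 against 18.3, reached 100 UMIs. Of 10091 genes with at least 100 UMIs, 12 were at least 2-fold higher and 32 at least 2-fold lower (14 and 61 in gated cells), from 3498 vaccine and 2229 vehicle cells. The intervals of all 40 named genes lay apart, which choosing genes by ratio favours, here and below.

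CD4 T-like cells of the WT vaccine library had lower levels of inhibitory receptor, activation and interferon response genes than those of the WT vehicle library. The inhibitory receptor genes Lag3, Tigit, Pdcd1 and Ctla4 were lower with vaccine, as were Tnfrsf4, which encodes the co-stimulatory receptor OX40, and Ikzf2, which encodes Helios, a factor of regulatory and chronically stimulated T cells. Genes of naive cells, among them Dapl1, Ccr7 and Lef1, were higher. With vaccine against vehicle, in CPM, Lag3 stood at 7.70 [4.70 to 11.9] against 41.7 [34.0 to 50.6], Tigit at 20.8 [15.6 to 27.1] against 89.1 [77.6 to 102], Pdcd1 at 19.6 against 75.2 and Ctla4 at 21.9 against 67.0. The exhaustion and inhibitory receptor list had a median log2 ratio of -1.24 over 12 members at percentile 0, with 10 members at least 1.5-fold lower. The median was -0.58 in cells with Y-linked UMIs only, -0.50 within T cluster 7 (4 members each) and -0.54 in gated cells, a group that takes in regulatory cells. Among activation genes Tnfrsf4 stood at 28.1 against 90.3, Tnfrsf18, which encodes GITR, at 81.2 against 131 and the adhesion receptor gene Cd44 at 78.9 against 119, with a list median of -0.38. The helper and regulatory program list had a median of -0.39, with Ikzf2 at 65.4 against 210.0 and Izumo1r, a folate receptor family gene of follicular and regulatory cells, at 94.3 against 185. Type I interferon response genes had a median of -0.28 over 36 members at percentile 0, with Isg20 at 24.6 against 54.3, Oas1a at 24.6 against 49.4 and Isg15 at 52.7 against 105. It was -0.095 and -0.45 in cells with Xist or Y-linked UMIs only, -0.13 within T cluster 8 and -0.12 in gated cells. Type II interferon genes had a median of -0.23, with the protease inhibitor gene Serpina3g at 42.3 against 79.3 and the MHC class I regulator gene Nlrc5 at 115 against 186. The naive and central memory list had a median of 0.22 at percentile 99.995, with Dapl1 at 225 against 127, Ccr7 at 426 against 311 and Lef1 at 998 against 742. It was -0.11 within T cluster 7, 0.13 and 0.47 in cells with Xist or Y-linked UMIs only and 0.34 in gated cells. Cell cycle genes had a median of 0.23, with the replication gene Mcm7 at 42.3 against 24.5 and Stmn1 at 87.8 against 55.2. The chemokine receptor gene Cxcr3 stood at 164 against 264 in a homing list with a median of -0.36. Cytotoxic effector genes had a median of -0.33, with Gzmk at 48.1 against 83.8 and S100a6 at 412 against 669, but 0.21 in cells with Xist UMIs only, -0.79 in cells with Y-linked UMIs only, -0.13 within T cluster 7, 0.027 within T cluster 8 and -0.57 as a mean over cells. Gzmb stood at 3.46 against 43.7, but 70 of its 107 vehicle UMIs lay in 1 cell. Sostdc1, which encodes a secreted signalling antagonist, stood at 1.15 [0.238 to 3.38] against 44.5 [36.6 to 53.7], with its 109 vehicle UMIs in 13 of 590 cells, and the transcription factor gene Tshz2 stood at 8.47 against 44.9. Ribosomal proteins had a median of 0.21 and mitochondrial transcripts -0.27. RNA of other cells was lower as well, with S100a8 at 6.54 against 29.8 and the immunoglobulin gene Igkc at 0.385 against 7.35 (1 against 18 UMIs). Of 6682 genes, 1 was at least 2-fold higher and 62 at least 2-fold lower (15 and 53 in gated cells, 5 and 116 as a mean over cells), from 538 vaccine and 590 vehicle cells. Intervals of 49 of the 59 named genes lay apart. Overlaps included Bcl6, Cxcr4, Cxcr5, Gata3, H2-DMa, Mcm2, Myc, S100a9 and mt-Nd3.

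The same treatment comparison in TCKO mice asked whether T cells without miR-155 differed with vaccine. CD8 T-like cells of the TCKO vaccine library had lower levels of interferon response and cell division genes than those of the TCKO vehicle library and higher levels of a few effector genes. The interferon-induced genes Rtp4, Isg15 and Oas3 and the mitosis genes Cdca8 and Top2a were lower with vaccine. Cx3cr1, which encodes the fractalkine receptor of effector cells, the effector transcription factor gene Zeb2 and the inhibitory receptor gene Lag3 were higher. In CPM, vaccine against vehicle, Rtp4 stood at 43.7 [41.1 to 46.3] against 69.0 [65.7 to 72.3], Isg15 at 27.4 against 37.8 and Oas3 at 16.8 against 23.1. The type I interferon list had a median log2 ratio of -0.19 over 42 members at percentile 0, with 1 member at least 1.5-fold lower, and -0.10 within T cluster 9. Type II interferon genes had a median of -0.11 at percentile 0.02, with the signalling inhibitor gene Socs1, a reported target of miR-155, at 90.9 against 114. Cell cycle genes had a median of -0.17 at percentile 0: Cdca8 stood at 1.84 against 3.58, Top2a at 2.66 against 4.88 and Mcm5 at 20.9 against 27.8, while the histone gene Hist1h2ap was higher at 3.56 against 1.75. Glycolysis genes had a median of -0.13, with Ldha at 446 against 528. The cytotoxic effector list had a median of 0.081 over 29 members at percentile 99.99, with Cx3cr1 at 9.46 [8.30 to 10.7] against 4.47 [3.67 to 5.39], Zeb2 at 21.1 against 10.2 and Prdm1 at 3.91 against 2.03 higher and Gzma, a granule protease gene, lower at 11.6 against 18.5, where 148 of 456 vehicle UMIs lay in 1 cell. That median was 0.14 in cells with Xist UMIs only and turned to -0.030 in gated cells, -0.055 in cells with Y-linked UMIs only, -0.16, -0.0089 and -0.017 within T clusters 1, 13 and 9 and -0.21 over 19 members without T cluster 9. Among helper genes Il12rb2 stood at 3.44 against 5.61 and Bcl6 at 15.0 against 11.9, and the list median of 0.18 turned to -0.036 in the gated cells. Medians were 0.022 for naive and central memory genes (-0.014 within T cluster 13), 0.049 for exhaustion genes (-0.029 in cells with Y-linked UMIs only), -0.052 for activation genes and 0.00080 for reported miR-155 targets. Among the largest ratios were the peptide transporter gene Slc15a2 at 104 [100.0 to 108] against 32.0 [29.8 to 34.3], Fam177a at 7.46 against 2.68, the semaphorin receptor gene Nrp1 at 3.91 against 1.58 and Lag3 at 3.44 against 1.54. On the lower side were Fos at 3.4 against 6.83 and Klra9 at 1.64 against 3.25. Stress genes had a median of -0.21, with Dnajb1 at 104 against 134, and mitochondrial transcripts 0.068. Neutrophil RNA was higher with vaccine, with S100a8 at 8.95 against 3.90 and S100a9 at 12.2 against 6.46. Of 10418 genes, 13 were at least 2-fold higher and 4 lower (16 and 22 in gated cells), from 3570 and 3093 cells. Intervals of 43 of the 49 named genes lay apart. Those of Hspa1a, Ifng, Iigp1, Ikzf2, Ngp and Oasl1 overlapped.

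In CD4 T-like cells of TCKO, interferon response genes were lower with vaccine. Effector genes were higher in the class but not within T clusters 7 or 8. S100a6, the protease inhibitor gene Cst7, the chemokine gene Ccl5 and Anxa2 were higher with vaccine, and Rtp4, Ifi206, Irgm1 and the naive cell gene Igfbp4 lower. With vaccine against vehicle, in CPM, S100a6 stood at 326 [306 to 347] against 217 [201 to 234], Cst7 at 41.3 against 27.8, Ccl5 at 1127 [1089.8 to 1165] against 763 [733 to 794] and Anxa2 at 74.9 against 53.7. Cytotoxic effector genes had a median log2 ratio of 0.29 over 15 members at percentile 100, with no member at 1.5-fold. It was 0.74 and -0.80 in cells with Xist or Y-linked UMIs only. It was 0.045 in gated cells and -0.22 and -0.17 within T clusters 7 and 8. Cluster 8 held 27.6% of the class with vehicle and 40.1% with vaccine. Type I interferon genes had a median of -0.18 over 38 members at percentile 0, with Rtp4 at 85.4 against 115 and Ifi206 at 82.6 against 111. The value was -0.086 and -0.35 in cells with Xist or Y-linked UMIs only, -0.32 within T cluster 7 and -0.097 in gated cells. Type II interferon genes had a median of -0.19, with Irgm1 at 55.0 against 82.5. In the naive and central memory list, with a median of -0.075, Igfbp4 stood at 124 [112 to 137] against 217 [201 to 234] and the chromatin organiser gene Satb1 at 460.1 against 539, and the median was -0.35 in cells with Xist UMIs only, 0.17 in cells with Y-linked UMIs only, 0.021 within T cluster 7 and 0.28 within T cluster 8. The activation list had a median of 0.12, with the NF-kappaB regulator gene Nfkbid at 38.4 against 23, and turned to -0.079 in gated cells. Cell cycle genes had a median of -0.14, with Rrm1 at 14.7 against 24.0, and exhaustion genes 0.089 over 6 members (-0.047 at minimums of 20 or 300 UMIs and -0.028 within T cluster 8). Among the largest ratios were Slc15a2 at 126 [114 to 139] against 57.6 [49.5 to 66.6] and the histone gene Hist1h4d at 38.1 against 18.5, and on the lower side Spryd7 at 10.6 against 21.4. Stress genes had a median of -0.079, with Dnaja1 at 315 against 409.6. Of neutrophil RNA, S100a9 was higher at 20.8 against 7.99, while S100a8, at 14.1 against 12.2, had intervals that overlapped. Of 7124 genes, 5 were at least 2-fold higher and 2 lower (17 and 10 in gated cells), from 631 and 609 cells. Of the 39 named genes 26 had intervals apart. Those of Cd44, Cd69, Gbp8, Hsp90aa1, Ifit1, Il2rb, Jun, Mcm2, Mcm3, Mcm5, Rrm1, Spg20 and Stat2 overlapped.

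The genotype comparison with vehicle asked what T cells lacking miR-155 expressed in leukaemia-bearing mice without vaccine. CD8 T-like cells of the TCKO vehicle library had lower levels of effector, inhibitory receptor and tissue-homing genes than those of the WT vehicle library and higher levels of interferon response genes. Klrg1, a receptor of late effector cells, the effector transcription factor gene Zeb2, Cx3cr1 and the egress receptor gene S1pr5 were lower in TCKO, as were the ectonucleotidase gene Entpd1 and the inhibitory receptor genes Lag3, Tigit and Pdcd1. The interferon-induced genes Oas2, Rtp4, Slfn5 and Oasl2 and the early response genes Nr4a1, Egr1 and Egr2 were higher. In CPM, TCKO against WT, Klrg1 stood at 3.05 [2.40 to 3.82] against 12.0 [10.3 to 13.8], Zeb2 at 10.2 [8.98 to 11.5] against 38.9 [35.8 to 42.2], Cx3cr1 at 4.47 against 16.5 and S1pr5 at 4.43 against 16.2. The cytotoxic effector list had a median log2 ratio of -0.78 over 29 members at percentile 0, with 18 members at least 1.5-fold lower and 0 higher. The median was -0.46 in cells with Xist UMIs only, -0.046 and 0.073 within T clusters 1 and 13, -0.33 within T cluster 9 and -0.20 over 19 members in the other CD8 T-like cells. Exhaustion and inhibitory receptor genes had a median of -0.27 over 14 members at percentile 0.36, with Entpd1 at 1.79 [1.30 to 2.40] against 8.21 [6.83 to 9.80], Lag3 at 1.54 against 5.41, Tigit at 3.05 against 10.1 and Pdcd1 at 2.11 against 6.41, and medians of -0.17 in cells with Y-linked UMIs only, -0.15, -0.0011 and -1.22 within T clusters 1, 13 and 9 and 0.048 without T cluster 9. Among helper genes, with a median of -0.32, Ifng, the interferon gamma gene, stood at 2.07 against 6.61 and Tbx21, which encodes T-bet, at 39.2 against 55.1. Homing genes had a median of -0.26, with Itga1 at 2.11 against 5.94 and Ccr2 at 17.1 against 36.3. Type I interferon response genes had a median of 0.21 over 42 members at percentile 100, with 39 members above 0: Oas2 stood at 3.86 [3.12 to 4.72] against 1.27 [0.764 to 1.98], Rtp4 at 69.0 against 40.0, Slfn5 at 30.7 against 18.5 and Oasl2 at 10.6 against 6.48. It was 0.42 and 0.42 within T clusters 1 and 9, 0.32 without T cluster 9 and 0.38 in gated cells. Type II interferon genes went both ways around a median of 0.082, with the GTPase gene Tgtp1 at 54.3 against 35.2 and Serpina3g at 13.6 against 24.1. In the activation list, with a median of 0.096, Nr4a1 stood at 30.4 [28.3 to 32.7] against 11.4 [9.71 to 13.2], Egr2 at 11.3 against 5.21 and Egr1 at 46.5 against 22. Egr1 and Nr4a1 were leading genes of T cluster 15 of the class, and 10 TCKO cells held 43.3% of the Nr4a1 and 41.5% of the Egr2 UMIs. The activation median turned to -0.025 as a mean over cells and -0.085 in gated cells. The cell cycle median turned from 0.25, with Tuba1b at 325 against 224, to -0.11 in gated cells. Reported miR-155 targets had a median of 0.051 over 20 members at percentile 79.0, naive and central memory genes 0.079, glycolysis genes 0.10 and MHC class I genes -0.062.

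The genes furthest apart between the genotypes with vehicle in CD8 T-like cells included Camk2b, higher in TCKO at 20.1 against 4.07, Haao, an enzyme gene of tryptophan breakdown, at 5.0 against 1.47, and Rasgef1b, a signalling gene, lower at 3.98 against 19.6. The heat shock genes Hspa1a and Hspa1b were lower in TCKO, at 3.17 against 13.2 and 10.5 against 30.4, while the stress list as a whole had a median of 0.19 at percentile 99.99. Mitochondrial transcripts had a median of -0.19 at percentile 0.01. Neutrophil RNA was lower in TCKO, with S100a8 at 3.90 against 12.9 and Camp at 1.42 against 6.34. Hbb-bs stood at 0.325 against 49.9, with 395 of 747 WT UMIs in 1 cell. Of 10152 genes, 13 were at least 2-fold higher and 76 lower (13 and 122 as a mean over cells), from 3093 TCKO and 2229 WT cells, and the intervals of all 59 named genes lay apart.

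In CD4 T-like cells with vehicle, inhibitory receptor, activation and effector genes were lower in TCKO than in WT and naive cell genes higher. The same WT library is the reference of the WT vaccine contrast. Lag3, Tigit, Pdcd1, Ctla4, Tnfrsf4, Xcl1, Cd44 and the co-stimulatory receptor gene Icos were lower in TCKO, and Dapl1 and Ly6c1 higher. With TCKO against WT, in CPM, Lag3 stood at 1.28 [0.348 to 3.27] against 41.7 [34.0 to 50.6], Tigit at 9.59 [6.47 to 13.7] against 89.1 [77.6 to 102], Pdcd1 at 8.63 against 75.2 and Ctla4 at 13.4 against 67.0. The exhaustion list had a median log2 ratio of -1.81 over 12 members, 11 of them at least 1.5-fold lower. The median was -0.41 in cells with Y-linked UMIs only (6 members), -0.71 within T cluster 7 (4 members) and -1.12 in gated cells. Tnfrsf4 stood at 18.2 against 90.3, Xcl1 at 15.3 against 44.5, Cd44 at 56.0 against 119 and Icos at 66.5 against 114 in an activation list with a median of -0.58. Xcl1 turned to a log2 ratio of 0.65 in gated cells. The helper and regulatory program list had a median of -0.57, with Ikzf2 at 41.6 against 210.0 and Izumo1r at 84.4 against 185. Homing genes had a median of -0.58, with Cxcr3 at 126 against 264 and the integrin gene Itgb1, a leading gene of T cluster 8, at 367 against 688. Effector genes of the cytotoxic list had a median of -0.89 over 14 members at percentile 0, with S100a6 at 217 against 669, S100a4 at 105 against 314 and Gzmk at 30.1 against 83.8. It was nearer 0 within the clusters, at -0.31 (percentile 5.54) in T cluster 7 and -0.067 (percentile 17.9) in T cluster 8, at -0.43 with no doublets removed and at -0.26 in gated cells. Naive and central memory genes had a median of 0.40 at percentile 100, with Dapl1 at 268 [250.1 to 287] against 127 [113 to 142] and Ly6c1 at 294 against 157. It was -0.015 and -0.067 within T clusters 7 and 8, 0.60 in cells with Y-linked UMIs only and 0.71 in gated cells. Type I interferon response genes had a median of 0.16 over 38 members at percentile 99.99, with 3 members at least 1.5-fold higher, such as Ifit3 at 65.9 against 36.8 and Usp18 at 52.1 against 29.4, and 4 lower, such as Isg20 at 25.3 against 54.3 and Isg15 at 61.7 against 105. That median was 0.41 and 0.38 within T clusters 7 and 8. It was 0.25 and -0.0091 in cells with Xist or Y-linked UMIs only and 0.32 in gated cells. Isg15 turned to a log2 ratio of 0.18 in gated cells. Cell cycle genes had a median of 0.26, with Mcm7 at 44.4 against 24.5 and Stmn1 at 85.1 against 55.2, and -0.94 in gated cells.

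The genes furthest apart in CD4 T-like cells with vehicle included Camk2b at 37.4 [30.9 to 44.8] against 5.72 [3.13 to 9.60], Ly6c2, a surface antigen gene, at 529 against 192 and Cd4 itself at 1001 [966 to 1036] against 364 [341 to 389], all higher in TCKO. Gpm6b, a membrane protein gene, stood at 5.76 against 95.2 and Tshz2 at 2.56 against 44.9. Sostdc1 had no UMI in the TCKO library, which with 3 UMIs in its place makes it at least 46.4-fold lower than the WT value of 44.5. Gzmb stood at 2.88 against 43.7, with the WT UMIs mostly in 1 cell. RNA of neutrophils was lower in TCKO, with S100a8 at 12.2 against 29.8. Ribosomal proteins had a median of 0.24, mitochondrial transcripts -0.19 and reported miR-155 targets -0.11 at percentile 16.2. Of 6970 genes, 14 were at least 2-fold higher and 131 lower (35 and 190 in gated cells), from 609 TCKO and 590 WT cells. Intervals of 47 of the 51 named genes lay apart. Overlaps included Bcl6, H2-DMa and Mcm5.

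The genotype comparison with vaccine asked whether miR-155 loss altered T cells of vaccinated mice. CD8 T-like cells of the TCKO vaccine library had lower levels of cytotoxic effector and inhibitory receptor genes than those of the WT vaccine library and higher levels of antigen receptor response genes. The granule protease gene Gzma, Klrg1, S1pr5, Tigit, Lag3 and Pdcd1 were lower in TCKO, and the nuclear receptor genes Nr4a1 and Nr4a3, Irf8, Egr2 and Xcl1 were higher. In CPM, TCKO against WT, Gzma stood at 11.6 [10.4 to 13] against 37.9 [35.4 to 40.6], Klrg1 at 2.74 [2.13 to 3.46] against 8.12 [6.97 to 9.40], S1pr5 at 7.04 against 16.5 and Gzmk, a leading gene of T cluster 9, at 32.4 against 71.5. The cytotoxic effector list had a median log2 ratio of -0.61 over 29 members at percentile 0, with 16 members at least 1.5-fold lower and 1 higher. It was -0.35 in cells with Y-linked UMIs only, -0.11, 0.014 and -0.42 within T clusters 1, 13 and 9 and 0.11 over 18 members without T cluster 9. Exhaustion and inhibitory receptor genes had a median of -0.19 over 15 members at percentile 0.17, with Tigit at 2.66 [2.06 to 3.37] against 7.53 [6.42 to 8.77], Pdcd1 at 3.56 against 8.67 and Lag3 at 3.44 against 9.67, for which 52 of 212 WT UMIs lay in 1 cell. Nr4a3, of the same list, was higher at 14.5 against 5.61, and the list median was -0.11 in cells with Y-linked UMIs only, 0.011, 0.083 and -0.56 within T clusters 1, 13 and 9 and 0.18 without T cluster 9. Activation genes had a median of 0.19 over 19 members at percentile 100, with 5 members at least 1.5-fold higher: Irf8 stood at 8.05 against 4.11, Nr4a1 at 24.1 [22.2 to 26.1] against 12.6 [11.2 to 14.2], Xcl1 at 56.6 against 32.6 and Egr2 at 12.3 against 7.43, though Egr2 had a log2 ratio of -0.0022 in gated cells. Few cells carried these UMIs: 10 cells of the TCKO library held 58.9% of those of Xcl1, 51.2% of Nr4a1, 51.1% of Nr4a3 and 45.2% of Egr2. An Xcl1 UMI was found in 274 of 3570 TCKO and 265 of 3498 WT cells. The type I interferon list had a median of 0.087 over 42 members at percentile 100, with Oas2 at 2.97 [2.34 to 3.72] against 1.14 [0.738 to 1.68], Oasl2 at 7.89 against 4.33 and Ifit3b at 4.92 against 2.96. The value was -0.021 in cells with Y-linked UMIs only, 0.14 and 0.30 within T clusters 13 and 9, 0.22 in gated cells and 0.15 with the interferon genes left out of clustering. Type II interferon genes had a median of -0.13 at percentile 0, with the transcription factor gene Irf1 at 142 against 170.4 and Serpina3g at 16.0 against 21.9, whose log2 ratio turned to 0.029 in gated cells. MHC class I genes had a median of -0.10, with B2m at 1664 against 1829.7, and of MHC class II genes Cd74 stood at 1.84 against 3.19 and H2-DMa at 41.7 against 50.2. Homing genes had a median of -0.26, with Ccr2 at 15.8 against 24.6 and Itgb1 at 81.2 against 107. Naive and central memory genes had a median of 0.043 (0.070 in cells with Xist UMIs only, 0.0036, 0.0083 and 0.26 within T clusters 1, 13 and 9), with Igfbp4 at 90.8 against 116 and Id3 at 74.8 against 64.3. Reported miR-155 targets had a median of -0.0095 over 21 members at percentile 81.2, ribosomal proteins 0.013, stress genes -0.065 and mitochondrial transcripts 0.074. Among the largest ratios were Slc15a2 at 104 [100.0 to 108] against 37.8 [35.2 to 40.4], the transcription factor gene Glis3 at 3.17 against 1.32 on the higher side, and the galectin gene Lgals3 at 3.09 against 11.8 on the lower. Of 10364 genes, 5 were at least 2-fold higher and 25 lower (11 and 22 in gated cells), from 3570 and 3498 cells. Of the 51 named genes 47 had intervals apart. Those of Gbp3, H2-Oa, H2-Ob and Iigp1 overlapped.

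CD4 T-like cells of the TCKO vaccine library had higher levels of interferon response genes than those of the WT vaccine library and lower levels of some effector genes. Ifit3, Oasl2, Usp18 and Rtp4, all induced by interferon, were higher in TCKO, as were Ly6c1 and Il7r, while S100a4 and Gzmk were lower. With TCKO against WT, in CPM, Ifit3 stood at 52.8 [45.0 to 61.5] against 25.4 [19.7 to 32.3], Usp18 at 48.6 [41.2 to 57.0] against 24.3 [18.6 to 31.0], Oasl2 at 26.2 against 12.7 and Rtp4 at 85.4 against 50.8. Genes of the type I interferon list had a median log2 ratio of 0.23 over 38 members at percentile 100, with 7 members at least 1.5-fold higher. The median was 0.11 in cells with Y-linked UMIs only. Cytotoxic effector genes had a median of -0.27 over 15 members at percentile 0, with S100a4 at 110.4 [99.1 to 123] against 215 [198 to 234] and Gzmk at 27.2 against 48.1. The median was -0.54 in cells with Y-linked UMIs only, -0.12 with no doublets removed and -0.029 in gated cells. Naive and central memory genes had a median of 0.077, with Ly6c1 at 288 against 169 and Il7r at 1512 against 1161, and were at 0.021 and 0.32 in cells with Xist or Y-linked UMIs only. Exhaustion genes had a median of -0.18 over 6 members, with the Notch effector gene Rbpj at 20.8 against 34.6, and -0.029 and -0.36 within T clusters 7 and 8, -0.50 in gated cells and -0.050 as a mean over cells. Among the largest ratios were Slc15a2 at 126 [114 to 139] against 29.3 [23.1 to 36.6], Ly6c2 at 544 against 260.2 and Cd4 at 748 against 361. On the lower side were Lgals3 at 10.6 against 34.6, the tissue residency gene Zfp683 at 8.96 against 27.7, Cd8a at 18.6 against 53.1, the receptor gene Slamf7 at 10.2 against 27.3, Xcl1 at 17.3 against 42.7 and Hspa1b at 17.6 against 40.4, of which Zfp683 and Xcl1 turned to log2 ratios of 0.19 and 0.42 in gated cells. In the WT library 24 of 538 cells had a Cd8a UMI, and 10 cells held 70.3% of the UMIs of Cd8a, 72.1% of Xcl1, 53.5% of Slamf7 and 80% of Lgals3. Medians were 0.025 for activation genes, -0.019 for type II interferon genes, -0.046 for reported miR-155 targets, 0.051 for ribosomal proteins and 0.093 for mitochondrial transcripts. Of 6876 genes, 7 were at least 2-fold higher and 13 lower (18 and 95 in gated cells, 3 and 1 at a minimum of 300 UMIs), from 631 and 538 cells. Intervals of 26 of the 33 named genes lay apart. Those of Id3, Klrd1, Maf, Tnf, Tox, Vsir and mt-Nd6 overlapped.

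**Figure D4:**
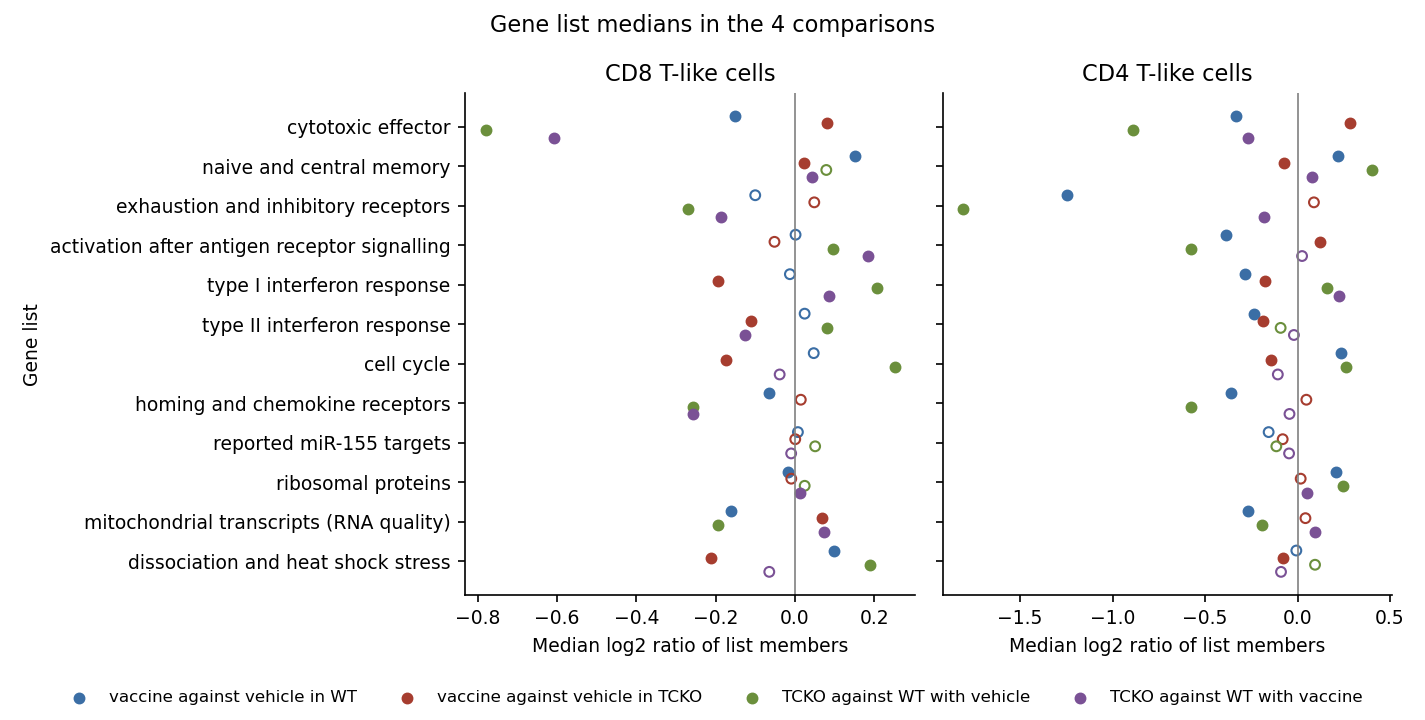
Median log2 ratio of list members (horizontal axis) for 12 gene lists (vertical axis) in CD8 and CD4 T-like cells, with a point per comparison, filled where the median lies under percentile 5 or over percentile 95 of random lists and open otherwise. The cytotoxic list lies at -0.78 and -0.61 in the genotype comparisons of CD8 T-like cells.

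To ask whether miR-155 loss altered the vaccine contrast, its log2 ratio in WT was subtracted from that in TCKO. In CD8 T-like cells this value was highest for the neutrophil genes S100a8 (1.98), Camp (1.98) and S100a9 (1.43) and for Rasgef1b (1.81). Among the lowest were Camk2b (-2.09), Greb1l (-1.81) and Fads1 (-1.16). In CD4 T-like cells the highest were Eea1 (2.36), Ctla4 (2.20), Tmem241 (2.10) and Ikzf2 (1.86), and among the lowest were Ints13 (-1.30), Pdlim1 (-1.27) and Ifngr2 (-1.21). For gene lists in CD8 T-like cells the median of the members' differences was 0.40 for cytotoxic effector, -0.16 for type I interferon, -0.19 for type II interferon, -0.29 for cell cycle and -0.36 for stress genes, and the cell cycle value turned to 0.14 in gated cells. In CD4 T-like cells it was 1.11 for exhaustion, 0.60 for activation, 0.57 for cytotoxic effector, 0.56 for helper, 0.51 for homing and -0.43 for cell cycle genes. Across 10062 genes of CD8 T-like cells the log2 ratios of vaccine against vehicle in WT and in TCKO had a Pearson r of 0.0778 (Spearman rho 0.00750), and across 6587 genes of CD4 T-like cells r was -0.0703 (rho -0.0520). For TCKO against WT with vehicle and with vaccine, r was 0.263 (rho 0.0971) in CD8 and 0.195 (rho 0.131) in CD4 T-like cells. Genes of a library are not independent replicates, nor are contrasts that share the WT vehicle library, and the genotype difference was not tested.

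The share of CD8 T-like cells with a UMI of a gene asked whether more cells or more transcripts per cell carried the effector program, after each cell was thinned to 1500 UMIs. The effector genes had their lowest shares in the TCKO libraries: Gzma 2.28, 0.649, 1.80 and 0.650%, Gzmb 2.28, 0.454, 1.83 and 0.678%, Gzmk 7.98, 2.17, 7.86 and 3.39%, Klrg1 1.60, 0.389, 1.26 and 0.537% and Cx3cr1 2.78, 0.746, 3.20 and 1.33%. Pdcd1 was found in 1.14, 0.0649, 1.29 and 0.565% and Tox, which encodes a factor of chronically stimulated cells, in 20.4, 14.1, 16.0 and 15.3%. The naive cell gene Tcf7 was found in more cells of the TCKO libraries, at 55.2, 63.3, 58.2 and 63.3%, and Cxcr3 was found in 11.2, 7.46, 7.78 and 7.57%. Of the 14 genes counted, intervals were apart for 9 lower and 2 higher in TCKO than in WT with vehicle, and for 6 lower and 2 higher with vaccine (5 and 0 when thinned to 1000 UMIs). For vaccine against vehicle they were apart for 2 lower and 0 higher in WT and for 0 lower and 3 higher in TCKO. Without thinning the shares were 2.83, 1.07, 2.49 and 1.48% for Gzma, 12.7, 4.07, 12.2 and 6.95% for Gzmk and 88.0, 96.4, 90.8 and 94.6% for Tcf7. The direction for Prf1, the perforin gene, depended on the thinning: the shares were 8.39, 6.10, 9.83 and 8.22% with it and 26.8, 29.9, 28.2 and 28.3% without it. Thinning left out 37, 11, 0 and 32 cells with fewer UMIs. In neutrophil-like cells, the background, thinned shares in the WT vaccine library were 3.55% for Klrg1, 12.4% for Tox and 22.5% for Tcf7, from a median of 4817 UMIs. There the Klrg1 share of CD8 T-like cells lay below this background.

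T cell receptor beta V gene usage asked whether vaccination went with a shift in the receptors used, as shares of all Trbv UMIs. In CD8 T-like cells of WT, Trbv12-1 made up 5.48% [5.19 to 5.78] with vehicle and 6.73% [6.48 to 6.99] with vaccine, Trbv1 8.57% and 7.45% and Trbv12-2 7.55% and 6.75%. In TCKO CD8 T-like cells Trbv12-2 made up 6.99% [6.74 to 7.25] with vehicle and 5.38% [5.17 to 5.61] with vaccine, Trbv13-1 7.93% and 8.94% and Trbv3 7.92% and 7.01%. By UMIs, larger differences were seen in the smaller CD4 T-like class. In WT, Trbv23 made up 4.38% [3.79 to 5.03] with vehicle and 0.806% [0.576 to 1.10] with vaccine, Trbv31 9.59% and 6.51% and Trbv5 1.55% and 3.36%. In TCKO, Trbv15 made up 3.87% [3.4 to 4.38] with vehicle and 8.54% [7.85 to 9.28] with vaccine, Trbv13-2 14.5% and 11.9% and Trbv1 11.2% and 9.14%. With cells counted by their leading Trbv gene, intervals of the named genes lay apart for Trbv12-1 in CD8 (7.48% and 9.86%) and Trbv23 in CD4 T-like cells of WT (4.62% and 0.771%) and overlapped for the others. Trbv15 in TCKO was 1.92% [0.960 to 3.4] and 4.38% [2.88 to 6.35], and Trbv1 there turned to 0.12 percentage points higher with vaccine. By UMIs, genes that differed by 1 percentage point or more numbered 2 in each genotype for CD8 T-like cells, and 7 in WT and 5 in TCKO for CD4 T-like cells.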

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

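Tests chosen only after the result was seen were those of sex, depth, Foxp3, T cluster 9, clustering without interferon genes, gamma delta cells and free RNA, of which only the predictions for gamma delta cells and for free effector RNA with vehicle were written before the test was run. The cluster 9 test at first removed that cluster, which takes out its cells and their expression alike, and was replaced by values within it.

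Gene lists drew attention where the median of vaccine against vehicle pointed one way in WT and the other way in TCKO, at opposite ends of random lists, and with 1 library per group none of these differences between the genotypes was tested. In CD8 T-like cells the median over members of the difference, TCKO minus WT, was 0.40 for cytotoxic effector genes (-0.15 in WT and 0.081 in TCKO). Mitochondrial transcripts, a sign of RNA quality, differed by 0.27 (-0.16 in WT and 0.068 in TCKO) and stress genes by -0.36 (0.098 in WT and -0.21 in TCKO). In CD4 T-like cells it was 0.57 for cytotoxic effector genes (-0.33 in WT and 0.29 in TCKO, yet 0.21 in WT cells with Xist UMIs only, and -0.80 in cells with Y-linked UMIs only and -0.22 and -0.17 within T clusters 7 and 8 in TCKO) and -0.26 for naive and central memory genes (0.22 in WT and -0.075 in TCKO). Activation genes there differed by 0.60 (-0.38 in WT and 0.12 in TCKO) and cell cycle genes by -0.43 (0.23 in WT and -0.14 in TCKO). Other medians named here also changed sign in splits, such as that of cytotoxic genes in CD8 T-like cells to 0.14 in WT cells with Xist UMIs only. Sex-linked RNA, which no comparison used, drew attention as a signal outside the main measurement: cells with a Y-linked UMI and no Xist UMI made up 25.3 (WT vehicle), 32.6 (TCKO vehicle), 11.5 (WT vaccine) and 13.2% (TCKO vaccine) of T-like cells.

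Regulatory T-like cells had their highest share in the WT vehicle library. A difference in the sexes sampled would place that library within the range of the others in cells of one sex, but its share was 19.3% in cells with Xist UMIs only and 16.8% in cells with Y-linked UMIs only, against 5.99 to 9.38% and 7.05 to 11.0% in the others. Depth stays open: the WT vaccine library (10.0%) matches in median UMIs but starts at 1757 UMIs per barcode against 501. Free Foxp3 RNA would appear in other cells, but 0.658% of neutrophil-like cells of the WT vehicle library had a Foxp3 UMI, against 15.6% of its T-like cells. These values argue against sex and free RNA. Fewer regulatory cells after vaccine and after miR-155 loss stays a hypothesis that 1 library per group cannot separate from depth or variation between mice.

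Type I interferon response genes were higher in CD8 and CD4 T-like cells of TCKO than of WT libraries. Unnamed T cluster 3, led by Isg15 and Ifit3, lay outside these classes and was a larger share of T-like cells in the TCKO libraries. In the sex with the lower value the median with vehicle was 0.22 in CD8 T-like cells, which argues against animals of one sex as the cause there, but -0.0091 in CD4 T-like cells (0.25 in cells with Xist UMIs only), where sex stays open. With vaccine it was -0.021 in CD8 T-like cells, where sex stays open too, and 0.11 over 18 members in CD4 T-like cells, with members too far apart to decide. Leaving the interferon genes out of clustering gave at least 0.15 in both classes and treatments, which argues against clusters formed on these genes. Loss of miR-155 acting only inside the cells that lost it would leave gamma delta T-like cells without Cd4, Cd8a or Cd8b1 UMIs, in which the Cre driver may have been silent, near 0, but their median was 0.48 with vehicle. A signal shared across T cells from outside them stays a hypothesis, and Cre activity at an earlier stage of gamma delta cells and variation between mice stay open.

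Cytotoxic effector genes were lower in CD8 T-like cells of TCKO than of WT libraries. Outside the class lay unnamed T clusters 4 and 10, led by Ccl5 and Ly6c2, with Cd8a in 52.0 and 32.5% of cells. In both sexes and with both treatments the median stayed below 0, nearest at -0.35, which argues against animals of one sex as the cause. Free effector RNA, summed over 9 genes in neutrophil-like cells of the WT libraries, was 147 CPM with vehicle (upper limit 175) against a difference of 2076 in CD8 T-like cells, and 957 with vaccine (upper limit 1016) against 1428. It cannot account for the whole difference, but with vaccine a part stays open. Fewer T cluster 9 cells alone would leave the median within that cluster near 0, but it was -0.33 with vehicle and -0.42 with vaccine. This argues against their number as the whole cause only if the cluster held a like mix of cells in each library. Effector genes such as Gzmk lead it, so this stays open. In the other CD8 T-like cells the median was -0.20 over 19 members with vehicle and 0.11 over 18 with vaccine. Fewer effector cells together with lower expression per cell, or another mix of cells within the cluster, as an effect of miR-155 loss stay a hypothesis that these libraries cannot separate from variation between mice.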

How the results depend on the processing

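The settings that left the interferon genes out of clustering and the splits by sex or cluster were tests chosen only after results were seen, and the others were planned. No paired analysis was possible because each group held 1 library and the labels pair none. Of 509 values of main results under an alternative, 417 stayed within counting error, spread of list members or 1.5 times the count, 91 moved further and 1 reversed. For a list median, a change of sign counts as reversed only where the main value lay under percentile 5 or over percentile 95. Among the values that stayed, exhaustion in CD4 T-like cells, vaccine against vehicle in TCKO, changed sign to -0.047 (0.089) at minimums of 20 and of 300 UMIs. Of 7265 values of single genes, other classes and other lists, 6082 stayed, 1147 moved and 36 reversed. Mir155hg in all T-like cells stayed within its intervals under 6 alternatives. The ranges that follow leave out the splits by sex and cluster. The median of cytotoxic effector genes of CD8 T-like cells ranged over -1.03 to -0.58 for TCKO against WT with vehicle and -0.75 to -0.24 with vaccine. The type I interferon median of those cells ranged over 0.17 to 0.38 and 0.065 to 0.22, and the regulatory T-like share of the WT vehicle library over 18.7 to 20.8%. The splits lay outside these ranges in places. With vehicle the cytotoxic median was -0.46 in cells with Xist UMIs only, 0.073 within T cluster 13 and -0.20 without T cluster 9, and with vaccine it was 0.11 without T cluster 9. The type I interferon median was -0.021 with vaccine in cells with Y-linked UMIs only and 0.42 with vehicle within T cluster 9, and that regulatory share was 16.8% in cells with Y-linked UMIs only. In what follows a value in parentheses is the main value. Alone, "in WT" or "in TCKO" stands for vaccine against vehicle and "with vehicle" or "with vaccine" for TCKO against WT. The cause was not tested unless one is stated.

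With a mitochondrial limit of 5%, CD8 T-like shares were 39.5, 49.3, 53.5 and 50.3%, and in the WT vehicle library the CD4 T-like share was 8.98% and the regulatory share 18.7%. With that limit 13 genes (20) differed 2-fold in CD4 T-like cells for TCKO against WT with vaccine, and exhaustion in gamma delta T-like cells, vaccine against vehicle in WT, was 0.070 (-0.29). Resolution 0.5 gave CD8 T-like shares of 31.8, 46.2, 45.2 and 46.1% and CD4 T-like shares of 3.79, 6.79, 4.48 and 5.06%, and resolution 2.0 gave CD8 T-like shares of 38.4, 50.9, 53.0 and 49.9%. A minimum of 500 genes gave 46.1% CD8 T-like cells in the TCKO vehicle library.

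With interferon genes left out of clustering, CD8 T-like shares were 50.1% (TCKO vehicle), 53.1% (WT vaccine) and 50.3% (TCKO vaccine). The type I interferon median for TCKO against WT was 0.29 (0.21) with vehicle and 0.15 (0.087) with vaccine in CD8 and 0.31 (0.23) with vaccine in CD4 T-like cells, and 4 genes (7) differed 2-fold in CD4 T-like cells for vaccine against vehicle in TCKO. With no doublets removed, the regulatory share of the WT vaccine library was 11.2%, and that CD4 T-like count was 11. The cytotoxic median of CD4 T-like cells, TCKO against WT, was -0.43 (-0.89) with vehicle and -0.12 (-0.27) with vaccine. The difference of the vaccine contrasts for type I interferon was 0.22 (0.13) in CD4 T-like cells, miR-155 targets in all T-like cells with vaccine were -0.018 (0.0044), and ribosomal proteins in neutrophil-like cells with vehicle -0.11 (0.18).

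Cells gated by their own UMIs include cells that the clusters left unnamed, and the CD4 gate takes in regulatory cells. CD8 shares were 53.1, 66.1, 64.6 and 63% and CD4 shares 17.5, 14.4, 11.6 and 14.2%. Numbers of genes at 2-fold were 75 (44) in WT and 38 (17) in TCKO for vaccine against vehicle in CD8 cells. In CD4 cells they were 27 (7) for vaccine against vehicle in TCKO, and 225 (145) and 113 (20) for TCKO against WT with vehicle and with vaccine. In gated CD8 cells, for vaccine against vehicle in WT, naive genes were at 0.29 (0.15), ribosomal proteins at 0.00080 (-0.018) and Hbb-bs at 2.57 (-3.62). In TCKO, cytotoxic genes were at -0.030 (0.081) and helper genes at -0.036 (0.18). For TCKO against WT with vehicle, activation was at -0.085 (0.096), type I interferon at 0.38 (0.21) and cell cycle at -0.11 (0.25). With vaccine, type I interferon was at 0.22 (0.087), Egr2 at -0.0022 (0.72), Serpina3g at 0.029 (-0.45) and Hbb-bs at 2.16 (-1.74), and the difference of the vaccine contrasts for cell cycle was 0.14 (-0.29).

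In gated CD4 cells, for vaccine against vehicle in WT, naive genes were at 0.34 (0.22), exhaustion at -0.54 (-1.24), type I interferon at -0.12 (-0.28) and Bbc3 at -0.12 (0.81). In TCKO, cytotoxic genes were at 0.045 (0.29), activation at -0.079 (0.12), type I interferon at -0.097 (-0.18) and Nfkbid at -0.098 (0.74). For TCKO against WT with vehicle, cytotoxic genes were at -0.26 (-0.89), naive at 0.71 (0.40), exhaustion at -1.12 (-1.81), type I interferon at 0.32 (0.16) and cell cycle at -0.94 (0.26), with Xcl1 at 0.65 (-1.54), Isg15 at 0.18 (-0.77) and Stmn1 at -0.30 (0.62). With vaccine, cytotoxic genes were at -0.029 (-0.27), exhaustion at -0.50 (-0.18) and type I interferon at 0.34 (0.23), with Igfbp4 at 0.0085 (-0.44), Zfp683 at 0.19 (-1.63) and Xcl1 at 0.42 (-1.31).

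A minimum of 20 UMIs admits genes with wide counting error and a minimum of 300 UMIs tests fewer genes, which by construction moves the counts. In the order of the 4 comparisons (vaccine against vehicle in WT, in TCKO, TCKO against WT with vehicle, with vaccine), the numbers at 2-fold with 20 UMIs were 259, 169, 412 and 209 in CD8 and 395, 182, 565 and 239 in CD4 T-like cells. With 300 UMIs they were 18, 6, 37 and 12, and 12, 2, 45 and 4. At 20 UMIs, miR-155 targets in all T-like cells with vaccine were at -0.011 (0.0044) and naive genes in neutrophil-like cells with vehicle at 0.050 (-0.35). At 300 UMIs, exhaustion in CD4 T-like cells with vehicle was at -1.25 (-1.81). Type I interferon in gamma delta T-like cells, vaccine against vehicle in WT, was at 0.012 (-0.15), exhaustion there with vaccine at -0.13 (0.19) and homing in neutrophil-like cells with vaccine at 0.11 (-0.41).

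With the mean over cells, 135 genes (89) differed 2-fold in CD8 T-like cells with vehicle and 121 (63) in CD4 T-like cells for vaccine against vehicle in WT. Activation in CD8 T-like cells with vehicle was at -0.025 (0.096). In CD4 T-like cells, cytotoxic genes were at -0.57 (-0.33) and naive genes at 0.30 (0.22) for vaccine against vehicle in WT, exhaustion with vaccine at -0.050 (-0.18) and the difference of the vaccine contrasts for cytotoxic genes at 0.82 (0.57). Other classes gave 0.043 (-0.17) for cytotoxic genes in regulatory T-like cells in WT, -0.0047 (0.050) for naive genes in all T-like cells in TCKO, and with vaccine -0.017 (0.0044) for miR-155 targets and 0.00090 (-0.67) for neutrophil RNA in all T-like cells and 0.054 (-0.36) for type I interferon in neutrophil-like cells. Naive genes in CD4 T-like cells, vaccine against vehicle in WT, were at 0.30 (0.22) with edgeR's TMM or DESeq2's size factors. The higher share of genes at 2-fold for vaccine against vehicle in TCKO was 88.2% and 87.5% with these factors and 42.1% in gated cells in CD8 (76.5%) and 83.3% with either in CD4 T-like cells (71.4%).

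Thinning to 1000 UMIs left 1 gene (2) with a lower share of cells for vaccine in WT. For vaccine in TCKO 2 (0) were lower without thinning and 1 in gated cells, and the Prf1 difference without thinning was -1.65 points there and 3.11 for TCKO against WT with vehicle, each opposite in sign to the thinned cells. Without thinning, cells of unequal depth are compared. Counting cells by their leading Trbv gene gave 4 (2) and 1 (2) genes that differ by 1 point in CD8 T-like cells of WT and TCKO and 3 (5) in CD4 T-like cells of TCKO, with Trbv1 there at 0.12 (-2.07). Depth limited CD4 more than CD8 T-like cells, with 6682 against 10091 genes at 100 UMIs in the WT vaccine contrast.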

Other observations

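No hypothesis tests were added here, and the genes below were chosen after their values were seen. Gene lists were read in regulatory and gamma delta T-like cells as well. In regulatory T-like cells, inhibitory receptor genes had a median log2 ratio of -0.40 for vaccine against vehicle in WT, with 4 of 12 members at least 1.5-fold lower, and -0.23 in TCKO, with 4 of 10. TCKO against WT gave -0.50 with vehicle and -0.45 with vaccine, the latter -0.57 in cells with Xist UMIs only and -0.077 (6 members, percentile 52.9) in cells with Y-linked UMIs only. Activation genes of the same cells had medians of -0.25, -0.41, -0.15 and -0.29 in that order of comparisons, and Foxp3 itself stood at 649, 632, 650.2 and 542 CPM in the WT vehicle, TCKO vehicle, WT vaccine and TCKO vaccine libraries. Type I interferon response genes were lower with vaccine in both genotypes, with medians of -0.19 in WT and -0.39 in TCKO in regulatory cells (-0.42 and -0.030 in WT cells with Xist or Y-linked UMIs only) and -0.15 and -0.38 in gamma delta cells (0.27 in WT cells with Y-linked UMIs only). For TCKO against WT they were 0.28 with vehicle and 0.078 with vaccine in regulatory and 0.41 and 0.12 in gamma delta cells, but -0.10 and -0.16 with vaccine in cells with Y-linked UMIs only. Over all T-like cells, which include dividing cells left unnamed, cell cycle genes were lower with vaccine in TCKO, with a median of -0.56 and 14 of 32 members 1.5-fold lower, against -0.13 and 0 in WT. T cluster 12, led by Hmgb2, Stmn1 and Mki67, was 1.80, 2.22, 1.91 and 1.15% of T-like cells in the library order above.

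Single genes set a library or genotype apart in several T-like classes. Slc15a2 stood at 47.5, 69.7, 55.4 and 199 CPM in regulatory and 40.4, 30.9, 35.7 and 99.7 in gamma delta T-like cells, in the library order above. Camk2b stood at 9.61, 52.4, 44.6 and 58.9 in all T-like cells, at 3.63, 73.5, 41.8 and 69.1 in those with Xist UMIs only and at 16.6, 38.2, 78.5 and 48.4 in those with Y-linked UMIs only. Cd4 was higher in TCKO within regulatory cells as well, at 247, 502, 226 and 496, a level on which the gate by Cd4 UMIs depends.

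Some values rested on few cells or on RNA of other cells. In the WT vehicle library 1491 of 1512 Jchain UMIs of T-like cells lay in 1 cell. Neutrophil-like cells had type I interferon medians of -0.40 for vaccine against vehicle in WT, -1.15 in TCKO, and 0.56 and -0.36 for TCKO against WT with vehicle and with vaccine. Those of the WT vaccine library also carried T cell RNA, with a Tcf7 UMI in 22.5% of cells after thinning.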
